A study of Homo sapiens with 4 samples.

How the data were processed

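RNA-seq and ribosome profiling (Ribo-seq) were each run on control MCF7 cells and on MCF7 cells treated with Nutlin-3a, giving 4 libraries in 4 groups with 1 library per group. Per the labels' protocols, the dose was 8 mM, in the unit written there, and the treatment lasted 20 h. That unit is in doubt, because Nutlin-3a is usually given at micromolar doses. The RNA-seq libraries are labelled as polyA RNA, and the Ribo-seq libraries were made from nuclease-protected fragments recovered from monosome fractions of cycloheximide-treated cells.

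The values analysed were FPKM (fragments per kilobase of transcript, scaled to the mapped reads of the library) computed by the authors and deposited as 1 table with a value per gene symbol and library. The table held 6898 genes, each with 1 Ensembl transcript identifier, and how these genes were chosen was not stated. Bowtie is named, without a version, per the submitters' processing notes; the genome build, the annotation, the counting rule, the handling of reads that match several places and the scaling factors were not given in the sources used here. The deposited FPKM values had 2 decimals and were never below 1. Between 8 and 52 genes per library stood at exactly 1, so a gene at 1 was treated as a gene at or below the lowest value listed, and its ratio as compressed. Whether 1 was a floor or had been added was not stated. Table columns were assigned to libraries by their names, with the columns marked rp taken as ribosome profiling.

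Sequencing depth is unknown, because the table gives no read counts. Low values were searched for the steps that whole reads would leave. Among the 85 genes between 1 and 3 FPKM in both RNA-seq libraries and the 90 genes in both Ribo-seq libraries, no log2 ratio between libraries, rounded to 2 decimals, occurred more than 3 times, and the median for 1000 shuffles was also 3. No counting interval could therefore be given for any value.

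For each gene, log2((FPKM + 1) in Nutlin-3a / (FPKM + 1) in control) was computed for RNA and for ribosome density. On this scale the difference of low genes is understated. The difference in translational efficiency was the Ribo-seq log2 ratio minus the RNA-seq log2 ratio, so that a positive value means more ribosome density per RNA in the Nutlin-3a libraries. Genes with a mean of at least 1 FPKM over the libraries compared were kept, a filter that removed no gene because of the lowest value of 1. With 1 library per group there was no test, no p-value and no standard error, and an interaction model over both kinds of library would have had no residual degrees of freedom. Genes at least 2-fold apart were counted in each direction. Agreement between RNA and ribosome density was described by Pearson and Spearman correlations across genes, which are not independent replicates, and by the overlap of the 2-fold sets against the number expected for independent sets.

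Before the data were examined, 20 gene lists were fixed: p53 target genes, DNA replication, mitosis, DNA repair, cytosolic ribosomal proteins, translation factors, ribosome biogenesis, oxidative phosphorylation, cholesterol synthesis, amino acid stress, oestrogen response, interferon response, lysosome and autophagy, endoplasmic reticulum chaperones, m6A machinery, replication-dependent histones, luminal epithelial markers, fibroblast markers, blood cell markers and common reference genes. List members were matched by symbol or older symbol, and 18 lists had measured members. Each list was described by its median, by the 95% interval of that median from binomial order statistics over its genes, and by the percentile of the median among 10000 random lists of the same size matched on mean level in 10 bins. These describe the 4 libraries and carry no replicate error. Genes were named by a rule fixed in advance: the 10 highest and 10 lowest log2 ratios among genes with a mean of at least 5 FPKM, up to 4 members of each list with the largest absolute ratio, and TP53, MDM2 and CDKN1A. Members named because they departed from the rest of their list were chosen after their values were seen.

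The median gene lay at -0.04 for RNA, -0.36 for ribosome density and -0.31 for translational efficiency. The ribosome density and translational efficiency values are therefore reported relative to the median of all genes, unless said to be as deposited. Alternatives tried were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, centring on the median gene, quantile normalization within each kind of library, thresholds of 1.5-fold and 3-fold and, for translational efficiency, the residual of a linear fit of the Ribo-seq on the RNA-seq ratio. Analysis without a pseudocount, translational efficiency relative to neighbouring genes and the correlation without the p53 target, DNA replication, mitosis and DNA repair lists were added after seeing the data. For the neighbours, 6856 of the 6898 genes were placed in order along the chromosomes by matching symbols to the RefSeq gene table of GRCh38.p14, which also gave the names of pseudogenes, and no coordinate was used otherwise.

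The calculations were tested on simulated values for the same 6898 genes with 200 genes planted at 3-fold, 100 in each direction, and a random spread of 0.2 on the log2 scale. Planted genes had a mean of at least 20 FPKM over the 4 libraries, so lower genes were not tried. At 2-fold the RNA step recovered 100 of the higher and 100 of the lower genes, the ribosome density step 100 and 99, and the translational efficiency step 99 and 100, with 0 other genes past 2-fold in each. The log2 ratios of the data had wider standard deviations across genes, 0.55, 0.77 and 0.50, and no shift of the median gene was simulated. The simulation therefore checks the arithmetic and gives no error rate for these data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.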

Results

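MCF7 is an established oestrogen receptor-positive human breast cancer cell line with wild-type p53. Nutlin-3a occupies the p53-binding pocket of MDM2, the ubiquitin ligase that marks p53 for degradation, and so stabilises p53. RNA level and ribosome density were measured in control cells and in cells given Nutlin-3a (20 h, 8 mM as written in the labels, a unit that is in doubt because micromolar doses are usual). RNA-seq reports the abundance of a transcript, and Ribo-seq sequences the fragments covered by ribosomes, so that their ratio, the translational efficiency, describes ribosome density per RNA. Each of the 4 combinations had 1 library, so no difference below has a replicate check. The 6898 listed FPKM values summed to 354916 in the control and 352288 in the Nutlin-3a RNA-seq library, and to 699217 and 542275 in the corresponding Ribo-seq libraries. Median values were 20.3 and 19.4 FPKM for RNA and 24.7 and 19.7 FPKM for ribosome density. Read depth is unknown.

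The first comparison asked which RNAs differed between the Nutlin-3a and control libraries. p53 target genes were higher in the Nutlin-3a library: all 32 measured members of the 50 listed had a log2 ratio above 0, and 20 were at least 2-fold higher. Their median log2 ratio was 1.34 (95% interval over genes 0.80 to 1.93), and the medians of 10000 level-matched random lists ran from -0.38 to 0.26. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 (transcript ENST00000448526), had the highest ratio of all genes with a mean of at least 5 FPKM, at 4.44, with 36.8 FPKM in control and 823 FPKM in Nutlin-3a. GDF15, a secreted stress cytokine, followed at 4.21, from 9.81 to 199 FPKM. TP53I3, a quinone oxidoreductase, and FDXR, the mitochondrial ferredoxin reductase, had log2 ratios of 3.50 and 3.43. MDM2 itself (ENST00000462284) stood at 33.0 FPKM in control and 265 FPKM in Nutlin-3a, a log2 ratio of 2.97. RPS27L, SESN1 and SESN2, the last pair being sestrins that restrain mTORC1, had ratios of 2.23, 2.13 and 2.03. The 10 highest genes also held 2 that were not on the list, the proline dehydrogenase PRODH at 2.71 and TSPYL2 at 2.18. TP53 RNA (ENST00000269305) was not higher, with 34.2 FPKM in control and 23.6 FPKM in Nutlin-3a, a log2 ratio of -0.52.

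Genes of cell division were lower in the Nutlin-3a RNA-seq library. All 37 measured mitosis genes of the 40 listed were at least 2-fold lower, with a median log2 ratio of -2.50 (-2.65 to -2.35). PLK1, a kinase required for mitotic entry and spindle assembly, was the lowest gene at -3.47, with 89.5 FPKM in control and 7.15 FPKM in Nutlin-3a. HMMR, KIF20A, CCNA2 and CDC20, which act in spindle organisation, cytokinesis, cyclin-dependent kinase activation and the anaphase-promoting complex, followed at -3.20, -3.09, -3.07 and -3.03. The proliferation marker MKI67 stood at 87.4 and 11.8 FPKM, a ratio of -2.79. Of 36 measured DNA replication genes 32 were at least 2-fold lower, with a median of -1.59 (-1.81 to -1.47). The replication initiation genes MCM10, ORC6 and ORC1 and the transcription factor E2F1 had ratios of -2.18, -2.16, -2.09 and -2.07. The 4 members within 2-fold were PCNA at -0.45, CCNE1 at -0.37, TYMS at -0.57 and LIG1 at -0.40. Among 23 measured DNA repair genes 20 were at least 2-fold lower, with a median of -1.59 (-1.71 to -1.16), including BRCA1 at -1.84 and BRCA2 at -1.90, and ATR, MSH6 and FANCM lay within 2-fold at -0.19, -0.75 and -0.77. All 10000 random lists had medians above those of these 3 lists.

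Across all 6898 genes 117 were at least 2-fold higher and 315 at least 2-fold lower in RNA. Ribosome biogenesis genes were lower, mostly by less than 2-fold. Their 36 measured members had a median log2 ratio of -0.47 (-0.58 to -0.37), 35 were below 0, and LYAR at -1.41 was the member past 2-fold. Amino acid stress genes, the targets of the ATF4 pathway, had a median of -0.35 (-0.56 to -0.17) over 17 genes. PHGDH, which starts serine synthesis, stood at -1.32, while STC2, also on the oestrogen response list, stood at 1.18. Lysosome and autophagy genes were higher in 24 of 26 cases, with a median of 0.35 (0.09 to 0.52), and the cathepsin gene CTSL1 at 1.23 was the member past 2-fold. Oestrogen response genes had a median of 0.20 with an interval that held 0 (-0.25 to 0.47), although FHL2, STC2 and IGFBP4 stood at 1.65, 1.18 and 1.12. Cytosolic ribosomal protein genes were close to their control level at 0.12 (0.06 to 0.17) over 66 genes, as were translation factors at -0.04 (-0.22 to 0.10) over 32. Medians of the remaining lists were -0.08 for 48 oxidative phosphorylation genes, 0.13 for 22 cholesterol synthesis genes, 0.35 for 8 interferon response genes, 0.07 for 18 endoplasmic reticulum chaperones and -0.14 for 11 m6A machinery genes, with intervals that held 0. Common reference genes had a median of -0.15 (-0.27 to -0.07), and TUBB, a tubulin gene used as a reference, was lower at -1.26.

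**Figure D1:**
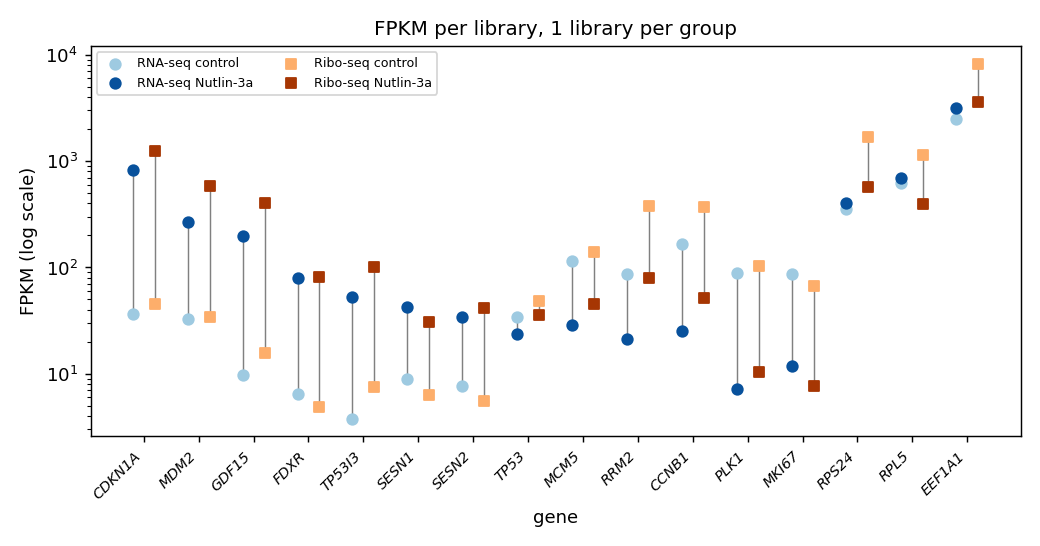
FPKM on a log axis for 16 genes in the RNA-seq libraries (blue circles) and Ribo-seq libraries (orange squares), control in the light and Nutlin-3a in the dark shade, 1 library per point and a line joining the 2 libraries of a kind. CDKN1A lies at 36.8 and 823 FPKM in RNA-seq, whereas for RPS24 the RNA-seq values nearly coincide at 357 and 403 FPKM and the Ribo-seq values lie apart at 1702 and 575 FPKM.

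The second comparison asked how ribosome density differed. The same groups stood out. Of the 32 p53 target genes 30 lay above the median gene and 24 were at least 2-fold above it, with a median of 1.34 (1.13 to 2.07) relative to all genes. The exceptions below the median gene were APAF1 at -0.18 and KITLG, the ligand of the receptor KIT, at -0.34. CDKN1A ribosome density was 44.9 FPKM in control and 1243 FPKM in Nutlin-3a, or 5.12 relative to the median gene. GDF15 stood at 4.97, MDM2 at 4.44, FDXR at 4.17 and TP53I3 at 3.94. PHLDA3, an inhibitor of Akt signalling, MXD4, a MYC antagonist, and ISYNA1, which makes inositol phosphate, were also among the 10 highest, at 3.13, 2.99 and 2.57. All 37 mitosis genes were at least 2-fold below the median gene, with a median of -2.59 (-2.79 to -2.45), led by HMMR at -3.33 and the kinetochore gene NDC80 at -3.19. DNA replication genes had a median of -1.47 (-1.73 to -1.25), with 28 of 36 at least 2-fold below the median gene, and DNA repair genes one of -1.44 (-1.92 to -1.13), with 18 of 23.

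Genes of the protein synthesis machinery had lower ribosome density. The 66 cytosolic ribosomal protein genes had a median of -0.52 (-0.67 to -0.35) relative to all genes, with 59 below the median gene. Translation factors had -0.54 (-0.84 to -0.26), with 27 of 32 below it, and ribosome biogenesis genes -0.64 (-0.86 to -0.29), with 28 of 36 below it, including the nucleolar genes NCL at -1.33 and NPM1 at -1.24. Luminal epithelial markers had a median of 1.12 (0.62 to 1.32), with 14 of 15 above the median gene. Lysosome and autophagy genes had 0.69 (0.25 to 0.96) and oestrogen response genes 0.64 (0.20 to 1.30). As deposited the medians of these last lists were 0.33 (-0.11 to 0.60) and 0.28 (-0.16 to 0.94), with intervals that held 0. The autophagy kinase gene ULK1 stood at 1.75, the lysosomal glucosidase gene GAA at 1.99, IGFBP4 at 2.46 and the cyclin D1 gene CCND1 at 1.51. The medians of oxidative phosphorylation, cholesterol synthesis, amino acid stress, interferon response, endoplasmic reticulum chaperone, m6A machinery and common reference genes were 0.12, 0.40, -0.16, 0.68, 0.25, -0.29 and 0.05, with intervals that held 0. The sign depended on the scaling for oxidative phosphorylation, chaperone and common reference genes, with -0.24, -0.11 and -0.31 as deposited. As deposited, 239 genes were at least 2-fold higher and 1127 at least 2-fold lower, and relative to the median gene 621 were higher and 497 lower. The lowest gene, HNRNPA1L2 at -4.36 as deposited, is a near-identical copy of HNRNPA1, and its value is uncertain because the handling of reads shared between copies was not given.

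The third comparison set ribosome density against RNA. Of the 117 genes at least 2-fold higher in RNA, 81 (69.2%) were also at least 2-fold higher in ribosome density as deposited, against 4.05 expected for independent sets. Of the 315 genes lower in RNA, 289 (91.7%) were lower in both, against 51.5 expected. Relative to the median gene of each comparison the shares were the other way round, with 121 of 132 genes (91.7%) higher in both and 253 of 309 (81.9%) lower in both. No gene was 2-fold apart in opposite directions (0 in each direction), and at 1.5-fold 1 gene was, the chromatin gene ARID4A, with 0.67 in RNA and -0.61 in ribosome density as deposited. Relative to the median gene of each comparison ARID4A was no longer among them, 0 genes were higher in RNA and lower in ribosome density, and 4 were lower in RNA and higher in ribosome density, OAS3, SLC19A1, C9orf142 and PGAM5. Across genes the log2 ratios had a Pearson correlation of 0.765 and a Spearman correlation of 0.658. Among the 6466 genes under 2-fold in RNA the Pearson correlation was 0.626, and without the members of the p53 target, DNA replication, mitosis and DNA repair lists it was 0.726 over 6770 genes.

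**Figure D2:**
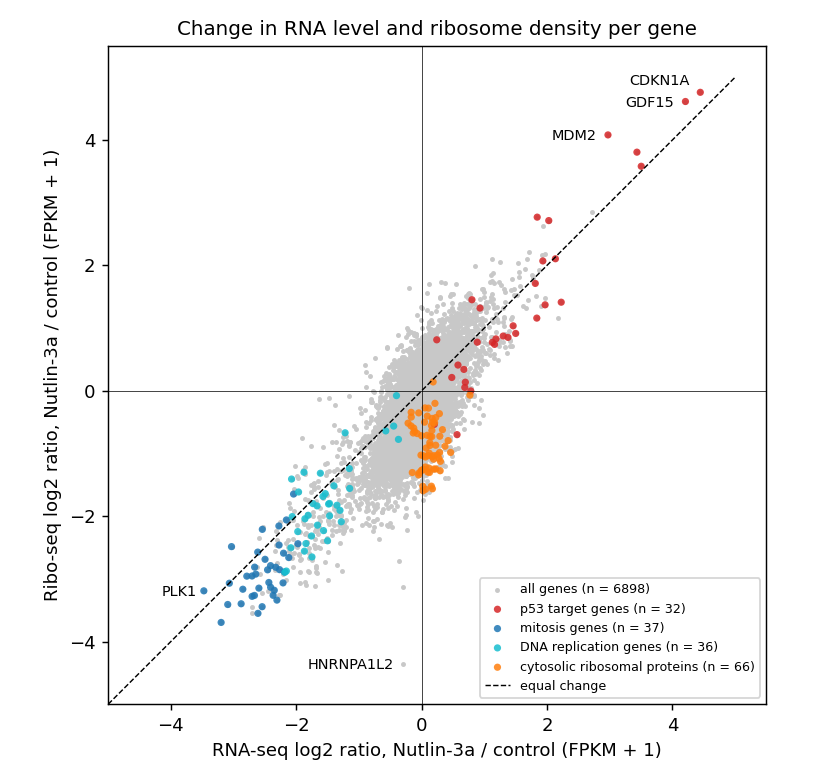
Log2 ratio of Nutlin-3a to control (FPKM + 1, as deposited) in RNA-seq on the x axis and in Ribo-seq on the y axis, 1 point per gene for all 6898 genes, with 4 gene lists coloured and a dashed line of equal ratios. p53 target genes lie at the upper right, mitosis and DNA replication genes at the lower left, and the 66 cytosolic ribosomal protein genes below the line, with medians of 0.12 in RNA and -0.88 in ribosome density.

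The fourth comparison concerned translational efficiency. Ribosomal protein genes and translation factors stood lowest among the lists. Their RNA was near the control level while their ribosome density per RNA was lower in the Nutlin-3a libraries. The 66 of 79 cytosolic ribosomal protein genes that were in the table had a median of -0.73 (-0.91 to -0.53) relative to all genes and -1.04 as deposited, 61 lay below the median gene, 14 were at least 2-fold below it, and 36 were at least 2-fold lower as deposited. RPS24, RPL5, RPL21 and RPS23 stood at -1.42, -1.37, -1.32 and -1.31. For RPS24 the RNA values were 357 FPKM in control and 403 FPKM in Nutlin-3a, and the ribosome density values were 1702 and 575 FPKM. The 5 members above the median gene were RPS28 at 0.27, RPL35 at 0.13, RPSA at 0.06, RPS2 at 0.01 and FAU at 0.01. Translation factors had a median of -0.55 (-0.81 to -0.32), with 26 of 32 below the median gene. The initiation factor gene EIF4B and the elongation factor genes EEF1G, EEF1B2 and EEF1A1 stood at -1.45, -1.25, -1.24 and -1.22, and EIF6, which holds ribosome subunits apart, at 0.62. The random lists had medians, as deposited, down to -0.62 for the ribosomal protein genes and -0.74 for the translation factors, above the list medians of -1.04 and -0.86. Many of these genes have processed pseudogenes, and how shared reads were assigned was not given.

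The groups with large RNA differences differed in the same direction in ribosome density, and relative to all genes they differed little in translational efficiency as groups. p53 target genes had a median of 0.01 (-0.21 to 0.45) relative to all genes, DNA replication genes 0.02 (-0.17 to 0.20), mitosis genes -0.09 (-0.24 to 0.06) and DNA repair genes -0.20 (-0.43 to 0.24). As deposited these medians were -0.30 (-0.53 to 0.14), -0.30 (-0.48 to -0.11), -0.40 (-0.55 to -0.25) and -0.52 (-0.74 to -0.07), and the last 3 intervals excluded 0. The DNA repair genes BRCA2, RAD54L, FANCB, BLM and EXO1 stood at the lowest listed value, 1 FPKM, in the Nutlin-3a Ribo-seq library. Their ribosome density ratios are compressed, so their translational efficiency values may be too high. With quantile normalization the p53 target and DNA replication medians were -0.07 and -0.02. Single p53 target genes departed from this: MDM2 stood at 1.42 and PHLDA3 at 1.24, and KITLG at -0.95 and RPS27L at -0.50. The value for CDKN1A was 0.63 and that for TP53 was 0.40, but as deposited they were 0.32 and 0.09. TP53 ribosome density was 48.7 FPKM in control and 35.9 FPKM in Nutlin-3a. Ribosome biogenesis genes had a median of -0.17 (-0.37 to 0.21), but -0.48 (-0.68 to -0.11) as deposited, with 30 of 36 below 0. Luminal epithelial markers had 0.56 (0.29 to 0.99), but 0.25 (-0.02 to 0.68) as deposited, with the secreted trefoil factor genes TFF3 and TFF1 at 1.35 and 1.10 and the claudin gene CLDN3 at 1.24. Oestrogen response, lysosome and autophagy, oxidative phosphorylation and interferon response genes had medians of 0.32, 0.29, 0.19 and 0.38, and cholesterol synthesis, amino acid stress and m6A machinery genes 0.04, 0.09 and -0.18. Endoplasmic reticulum chaperones had a median of -0.31 as deposited, the same as the median gene, and common reference genes one of 0.16. The intervals of these last 9 lists held 0 on the relative scale, and as deposited their medians lay between -0.50 for m6A machinery and 0.07 for interferon response genes. Apart from oestrogen response, interferon response and m6A machinery genes, the signs of these medians depended on the scaling. Across all genes, 45 were at least 2-fold higher and 391 at least 2-fold lower as deposited, and 200 were higher and 95 lower relative to the median gene, so that the balance of the directions rests on the scaling.

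Among single genes, the highest translational efficiency differences were those of EXOSC6, a subunit of the RNA exosome, at 2.15, the growth factor gene CLEC11A at 1.90, PAQR4 at 1.82 and BCAS4 at 1.77. PAQR4 RNA was lower, at 43.7 FPKM in control and 13.4 FPKM in Nutlin-3a, while its ribosome density was 8.97 and 8.08 FPKM. After HNRNPA1L2 at -3.75, the lowest were the nucleosome-binding protein gene HMGN5 at -2.52, the RNA polymerase III subunit gene POLR3G at -2.05, the histone chaperone gene NAP1L1 at -1.68 and the splicing factor gene PRPF38B at -1.63. HMGN5 and POLR3G had low RNA, at 6.57 and 6.66 FPKM in control and 5.14 and 4.97 FPKM in Nutlin-3a. Their ribosome density was 40.1 and 39.9 FPKM in control and 3.69 and 5.21 FPKM in Nutlin-3a. NAP1L1 RNA was 159 FPKM in control and 135 FPKM in Nutlin-3a, and its ribosome density was 906 and 192 FPKM.

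**Figure D3:**
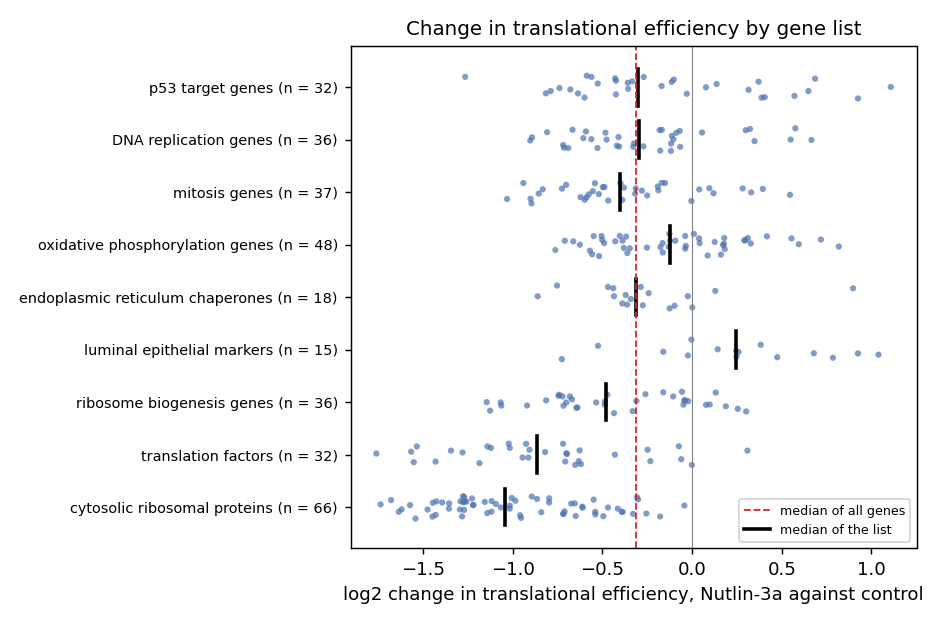
Log2 difference in translational efficiency (Ribo-seq minus RNA-seq log2 ratio, Nutlin-3a against control, as deposited) on the x axis for 9 gene lists, 1 point per gene, with a black bar at the median of each list and a red dashed line at the median of all genes, -0.31. Cytosolic ribosomal proteins and translation factors have the lowest medians, -1.04 and -0.86, and luminal epithelial markers the highest, 0.25.

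Within each condition only the rank of genes was read, since the kinds of library were scaled separately. The median ribosomal protein gene stood at percentile 72.6 of translational efficiency in control and at percentile 43.9 in Nutlin-3a, and translation factors at 67.9 and 52.6. In Nutlin-3a, oestrogen response genes at 41.7 and 67.5 and luminal epithelial markers at 67.7 and 88.9 ranked higher than in control. As fixed, these lists share TFF1, TFF3, XBP1 and ESR1, so they are not separate groups. Endoplasmic reticulum chaperones, which are translated at the endoplasmic reticulum, ranked high in both conditions, at 88.7 and 86.0, as did oxidative phosphorylation genes at 85.1 and 88.3. The median common reference gene stood at 70.6 and 54.5. However, 11 of the 17 reference genes lay above the median gene in the difference of translational efficiency, so these ranks do not describe that list. The median m6A machinery gene stood at 54.7 and 33.2, with 5 of the 11 genes above the median gene in that difference and 6 below it. p53 target genes ranked at 45.4 and 51.4 and mitosis genes at 60.8 and 55.3. Translational efficiency correlated between the conditions across genes, with a Pearson correlation of 0.876.

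The cell type markers with the highest values were those of luminal epithelium, although the fibroblast marker COL3A1 was abundant too. KRT8 had the highest RNA value in both RNA-seq libraries and KRT18 the highest ribosome density in both Ribo-seq libraries. Luminal markers were higher in Nutlin-3a RNA, with a median log2 ratio of 0.40 (0.11 to 0.52) over 15 of 18 genes; KRT19 stood at 1.03 and ELF3 at 0.96, and EPCAM at -0.48 was the exception. Of 18 fibroblast markers 6 were measured, with medians of 0.33 for RNA and, relative to all genes, 0.40 for ribosome density and 0.20 for translational efficiency, and intervals that held 0. As deposited the last 2 were 0.04 and -0.11, so the sign for translational efficiency depended on the scaling. COL3A1 was the abundant one, at 589 FPKM in control and 827 FPKM in Nutlin-3a, while COL1A1 and VIM stood at 1.74 and 2.79 FPKM in control. Of 18 blood cell markers and of 21 replication-dependent histone genes, 0 were among the genes analysed here.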

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

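The tests in this part were chosen after the pattern had been seen and before their own results were, apart from the comparisons at a similar number of pseudogenes, which were chosen after.

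Among the lists, cytosolic ribosomal protein genes were flagged because their RNA and ribosome density medians had opposite signs. Their RNA median was close to the control level, so the pattern rests mainly on ribosome density. Endoplasmic reticulum chaperones also had opposite signs as deposited, but with smaller medians, 0.07 and -0.11. For the ribosomal protein genes the median log2 ratio was 0.12 in RNA and -0.88 in ribosome density, and relative to all genes the values were 0.16 and -0.52. With 1 library per group the difference between the kinds of library was not tested against replicates.

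Among the explanations for the lower ribosome density per RNA of these genes, reads shared with processed pseudogenes were weighed on other genes: 196 genes outside the ribosomal protein and translation factor lists with at least 5 named pseudogenes (median 7) had a median of -0.10 relative to the 5438 genes with none (interval -0.19 to -0.01), against -0.76 for the ribosomal protein genes (median 16.5 pseudogenes). From 5 pseudogenes to below 16.5, 31 ribosomal protein genes had a median of -0.96 (-1.14 to -0.65) as deposited and 168 other genes one of -0.35 (-0.46 to -0.27), which argues against shared reads as the whole cause, whereas above 16.5 the medians were -1.27 (-1.35 to -0.95) over 33 ribosomal protein genes and -0.59 (-0.95 to 0.00) over 28 others, so a part may come from shared reads. In the lower range the sets had medians of 10 and 7 pseudogenes and were not matched on level, which limits that argument. A trend along the chromosomes, used in place of base composition, left the ribosomal protein genes -0.77 (-0.87 to -0.66) below their neighbours. The median of those neighbours was -0.24 as deposited, against -0.31 for all genes. However, the Spearman correlation between neighbours, 0.45, was under the minimum of 0.5 set beforehand for this test to decide. The base composition of the messages was not measured either, so that explanation stays open. Control of messages that start with an oligopyrimidine tract is the biological explanation that the treatment leaves open. Such control places ribosomal protein and several factor messages under mTORC1. The 11 translation factor genes listed beforehand as known to have the tract had a median of -0.49 relative to 21 others. The medians were -1.18 (-1.57 to -0.71) and -0.70 (-0.94 to -0.25), and their intervals overlapped. No sequence was used to check either set, so the others may include genes with the tract. These sets also differed in RNA, with median log2 ratios of 0.22 and -0.13. The upper end of the first interval, -0.71, was the value of HNRNPA1, a ribonucleoprotein gene whose reads may be shared with its copy. EEF2 at -0.82 and EIF3F at -0.63, of the same set, also lay above -0.94, the lower end for the others. Without sequences of the messages, base composition and tract control both stay open.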

How the results depend on the processing

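Analysis without a pseudocount, translational efficiency relative to neighbouring genes and the correlation without the p53 target and cell division lists were chosen after seeing the data. A filter cannot change the ratio of a single gene, no filter and the mean of at least 1 FPKM kept the same genes, and centring cannot change a correlation, so these are left out of the totals. Over the other alternatives, 297 list medians stayed within their interval, 59 moved outside it and 4 whose interval excluded 0 changed sign. Counting lists whose interval held 0, 36 of the 360 list medians under an alternative changed sign. They included 11 of 54 with centring and 9 of 54 with quantile normalization. For translational efficiency alone they included 7 of 18 with the regression residual and 6 of 18 relative to neighbouring genes. Of the values of single genes, 1257 stayed on their side of 2-fold, 123 crossed it and 0 changed sign from past 2-fold. Of the counts, 24 stayed within 1.5-fold and 28 did not. The 28 include 6 at the 1.5-fold and 6 at the 3-fold threshold, where the changed threshold itself moves the count. The 6 correlations of RNA with ribosome density lay between 0.726, without the p53 target and cell division lists, and 0.771. Pseudocount 0.1 gave mitosis medians of -2.72 (RNA) and -3.15 (ribosome density), and no pseudocount -2.75 and -3.16. Pseudocount 5 gave DNA replication medians of -1.37 and -1.59, mitosis medians of -1.99 and -2.51, ribosome density counts of 151 higher and 727 lower, and translational efficiency counts of 28 and 196, since it compresses low values. Centring on the median gene gave ribosome density counts of 621 and 497, DNA replication and mitosis medians of -1.47 and -2.59, translational efficiency counts of 200 and 95, and translational efficiency medians of -0.73 (ribosomal proteins), -0.55 (translation factors) and 0.015 (DNA replication, sign changed). Quantile normalization gave ribosome density counts of 592 and 506, medians of -1.51 and -2.62, translational efficiency counts of 163 and 103, and medians of -0.49, -0.52 and, for endoplasmic reticulum chaperones, 0.067 (sign changed). The regression residual gave counts of 174 and 112 and medians of -0.78, -0.59, 0.12 (DNA replication, sign changed) and 0.063 (mitosis, sign changed). Relative to neighbouring genes the counts were 104 and 117 and the medians -0.77 and -0.59. At 1.5-fold the counts were 466 and 698 for RNA, 713 and 2547 for ribosome density and 330 and 1984 for translational efficiency; at 3-fold they were 31 and 168, 45 and 324, and 2 and 28. The sign change of the DNA replication genes under centring follows from removing the shift of the median gene. The linear fit removes a shift through its intercept as well, and its slope of 1.08 raises the residual of lists with low RNA ratios. Quantile normalization also removes a shift between libraries of a kind. How much each step contributed was not separated, and the cause of the remaining sign changes was not tested. Depth is unknown and no library could be left out, so the precision of single genes is not known.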

Other observations

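The gene families in this part and the test of a regional trend in the RNA-seq libraries were chosen after the results were seen.

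In all, 14 families defined by their symbols add to the lists. Heterogeneous nuclear ribonucleoprotein genes, which package and splice RNA, had a median RNA log2 ratio of -0.46 (-0.56 to -0.29) over 18 genes, HNRNPA1 of the translation factor list among them, and relative to all genes ribosome density of -0.78 and translational efficiency of -0.35. Chaperonin subunits, which fold actin and tubulin, had -0.46 in RNA with all 8 below the median gene, and -0.68 in ribosome density relative to all genes. Mitochondrial ribosomal protein genes had -0.25 (-0.31 to -0.19) in RNA over 61 genes, and a translational efficiency median of 0.10 (-0.06 to 0.25) relative to all genes, or -0.21 as deposited, against -0.73 and -1.04 for their cytosolic counterparts. Proteasome subunits had -0.22 in RNA over 33 genes, with 31 below the median gene. Kinesins and mini-chromosome maintenance genes, which share members with the fixed lists, had RNA medians of -1.61 and -1.54. Vacuolar ATPase subunits, which acidify lysosomes, had 0.22 (0.03 to 0.32) over 15 genes, coatomer subunits 0.28 (0.10 to 0.58) over 6 and the 4 keratins 0.52. Quantile normalization sets the RNA ratios of KRT8 and KRT18, the highest genes of both RNA-seq libraries, to 0 by construction.

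In translational efficiency relative to all genes, genes with ZNF symbols had a median of -0.19 (-0.25 to -0.07) over 138 genes. The intervals held 0 for DEAD-box helicases at -0.31 (-0.48 to 0.04) over 28 genes, serine/arginine-rich splicing factors at -0.14 (-0.65 to 0.32) over 9, Rab GTPases at -0.06 (-0.33 to 0.17) over 32 and solute carriers at 0.16 (-0.01 to 0.33) over 103.

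Differences in translational efficiency were shared between neighbouring genes. The Spearman correlation between a gene and the median of up to 5 genes on each side was 0.45 over 6856 genes, against at most 0.05 in 1000 shuffles, and genes that shared the first letters of their symbol were not used as neighbours. The same value was 0.33 for ribosome density and 0.062 for RNA, the latter just above the highest of its own shuffles, 0.057. A weak regional trend was thus present in RNA. The ribosome density ratio used the Ribo-seq libraries only, so its trend cannot come from the RNA-seq libraries. How far the RNA trend adds to that in translational efficiency was not separated. Base composition varies along chromosomes, and a difference between the Ribo-seq libraries in how they recovered fragments by base composition may therefore underlie part of the spread, a hypothesis that was tested only through neighbours, because no genome sequence was used here. A biological effect of the treatment on neighbouring genes was not tested separately.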
